A study of Mus musculus with 36 samples.

How the data were processed

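Tumour RNA of 12 mice and faecal 16S rRNA gene amplicons (V3 to V4) of 24 mice were taken as the authors deposited them, as a table of FPKM per gene and a table of ASV read counts with a taxonomy. The deposited tumour values are in FPKM, and the deposited faecal values are counts of reads per ASV. Per the submitters' processing notes, tumour reads were aligned to the mouse genome mm10 with HISAT2, assigned to genes with featureCounts and processed with DESeq2, and faecal reads were trimmed with cutadapt, all without versions. The denoising tool and the taxonomy database of the ASVs are not stated. Of 2016 ASVs 4 had no taxonomy, with 20 reads or 0.00186% of all reads.

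Multiplied by gene length and library size, 100% of the non-zero FPKM values were whole reads within 0.01 read, and the library size in the FPKM equalled DESeq2's size-factor scaling, at 0.956 to 1.03 of the library totals. Reads recovered in this way served only for tests chosen after the data were seen, edgeR and DESeq2 on 15123 genes. Recovered totals ran from 15881708 to 18218389 per tumour, and faecal totals averaged 39722 in control, 48966 in TSME, 44421 in αPD-L1 and 46202 in combination mice. Bounds for taxa without reads rest on 3 reads per group, 0.00126%, 0.00102%, 0.00113% and 0.00108% in that order, and cover counting error only, since PCR reads without molecular tags are not independent.

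Analysis used R 4.3.3 with limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and the data.table package (version 1.17.8), and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Groups, comparisons, gene lists, tests and most alternatives were fixed from the labels before the data were examined. Genes with at least 1 FPKM in at least 3 of 12 tumours (12682 of 54532; 25750 were 0 everywhere) were tested on log2(FPKM + 1) with limma, 1 coefficient per group, eBayes with a trend, and Benjamini-Hochberg adjustment at 0.05. Of 31 gene lists (465 genes, 7 of them not in the table), 25 with at least 5 tested genes went into camera with a preset correlation of 0.01, which compares a list with all other genes. Alternatives were camera with an estimated correlation and fry, which asks whether a list moves one way on balance without comparing it with other genes. Named genes were up to 10 passing genes per direction with the largest changes, a proper gene name, a mean of at least 5 FPKM in the higher group and no overlap between groups. Where fewer than 5 passed in a direction, the genes with the smallest p filled up to 5 under the same filters and are given as not passing. Added were the 2 members with the smallest p of each called list and 14 tested focus genes, of which 1 entered the tests and their adjustment but is not reported here. Genes named for single tumours, those called by DESeq2, and Nlrp3, Nfkbia and Irak3 were chosen after their values were seen. Comparisons that share control tumours share the chance values of those tumours.

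Faecal reads were summed per genus, with ASVs lacking a genus kept under their lowest named rank (200 groups). The 66 groups kept by filterByExpr held 99.4% of reads and were tested with edgeR's quasi-likelihood test after TMM scaling (factors 0.667 to 1.71, common dispersion 2.41). Diversity and pairwise PERMANOVA used all 924 regroupings of 6 and 6 mice (smallest two-sided p 0.00216), or 64 within mouse numbers (smallest p 0.0312). PERMANOVA over 4 groups used 10000 permutations, and 2000 with 1 sample left out. Exact permutation of phylum shares, and of genus shares adjusted over the 14 fixed genera tested, was chosen after the data were seen.

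The tests were tried on simulated data. With 200 of 12431 genes changed in 3 runs, limma recovered 80.5% at 2-fold (5.8% of calls false) and 94.2% at 4-fold (5.7%). These shares are over all changed genes. The median SE of log2 fold changes in the real data was 0.118 for combination against αPD-L1. Genes with a much larger SE, such as Gzmb and Cd274, may be recovered far less often. With 12 of 66 genera changed in 20 runs, edgeR recovered 0.5% at 2-fold, 2.4% at 4-fold (28.6% of calls false) and 44.2% at 16-fold. Alternatives covered pseudocount, filters, scaling, weights, trend, fits on 2 groups, other tools, taxonomic level, distances, blocks by mouse number and each sample left out. Left out were the untested lists (NK cells, regulatory T cells, Th17, B cells, Wnt targets, skin keratinocytes) and any pairing of tumours with faeces.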

Results

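Gene expression was measured in subcutaneous tumours of CT26, a colon carcinoma line of BALB/c mice, and the bacteria of the gut were measured in faeces of tumour-bearing mice, under 4 treatments. Mice were untreated (control), were given a bacterial mixture that the labels call tumor-suppressing multi-enterobacteria (TSME; its members are not named), received an antibody against PD-L1, the ligand that holds back T cells (αPD-L1), or received both (combination). RNA of 12 tumours was sequenced, 3 per group, and 16S rRNA gene amplicons of 24 faecal samples were sequenced, 6 per group. The tumour libraries held 15881708 to 18218389 reads assigned to genes, recovered from the deposited FPKM values, and the faecal samples held 35605 to 70539 reads in 2016 amplicon sequence variants (ASVs). Of 54532 annotated mouse genes, 12682 reached 1 FPKM in at least 3 tumours and were tested, 11054 of them protein coding. Tumours of all groups resembled each other closely, with Pearson correlations across genes from 0.937 to 0.988 between libraries. The tumour columns carry no mouse number that ties them to a faecal sample, so tumours and faeces were compared only by group.

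One combination tumour, PDL1TSE18, stood apart from the other 11 and carried many of the differences between groups. The first principal component held 33.5% of the variance and separated this tumour, whose median correlation with the others was 0.946. It held genes of antibody-producing plasma cells at levels seen in no other tumour: the immunoglobulin light chain gene Igkc was at 2129 FPKM against 3.39 to 108 elsewhere, the joining chain gene Jchain at 84.1 against 4.0 at most, and Mzb1 at 19.7 against 1.73 at most. Muscle actin Acta1 reached 175 FPKM against 43.2 at most elsewhere, and the collagen gene Col1a1 409 against 192. The means of most lists were also highest in this tumour. Among them were the T cell, cytotoxic, MHC class II, interferon gamma, fibroblast and skeletal muscle lists. So were the macrophage, dendritic cell, endothelial and adipocyte lists, while the proliferation and oxidative phosphorylation lists were lowest in it. A different combination tumour, PDL1TSE23, held the highest neutrophil list mean, with S100a9 at 149 FPKM against 16.1 at most elsewhere and the neutrophil attractant Cxcl2 at 23.2 against 4.32.

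**Figure D1:**
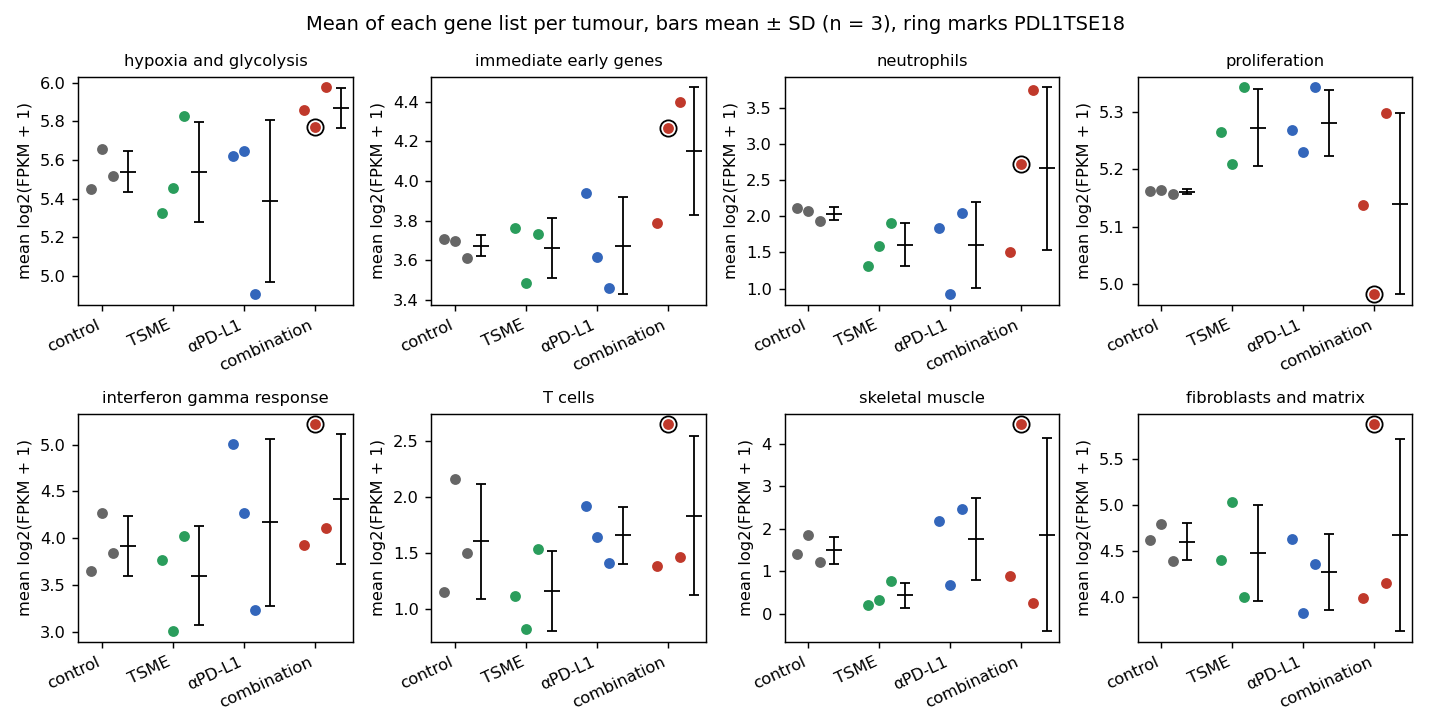
Mean log2(FPKM + 1) of 8 gene lists in each of the 12 tumours, with group mean and SD (n = 3 per group). The ring marks PDL1TSE18, which lies highest for T cells, interferon gamma response, skeletal muscle and fibroblasts and lowest for proliferation.

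The combination was compared with control to ask what both treatments together did to the tumour. The genes with the smallest p were Tnfsf9, the 4-1BB ligand that costimulates T cells (log2 fold change 0.69, SE 0.12), the retinoic acid receptor Rara (0.40, SE 0.08), the stress-response gene Ier5 (0.60, SE 0.12), Pnrc1 (0.61, SE 0.14) and Nfil3, a regulator of lymphocyte development (0.68, SE 0.16). Toward lower values lay mt-Tn, a mitochondrial transfer RNA (-1.66, SE 0.37), Eny2, Zfp120, Vamp7 and Magoh. None of these genes passed: limma called 0 of 12682 genes (smallest adjusted p 0.805). At an unadjusted p under 0.05 lay 775, where chance gives 634 in this and in each other comparison. Of 10 splits of these tumours, the real one included, 4 gave as many (highest other 1124). EdgeR and DESeq2 on recovered reads also called 0, with 782 of 15123 genes at an unadjusted p under 0.05 in edgeR. Nos2, the inducible nitric oxide synthase of activated macrophages, had a log2 fold change of 2.05 (SE 0.73), with 27.3 and 25.0 FPKM in PDL1TSE18 and PDL1TSE23 but 2.72 in the remaining combination tumour, against 1.52 to 4.43 in control.

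As groups, 7 of 25 gene lists fixed beforehand stood higher in the combination than in control relative to all other genes, in limma's camera test with a preset correlation between genes. With a correlation estimated from the data none of the 7 lists passed in camera, with adjusted p from 0.573 to 0.96. Immediate early genes, which respond within minutes to stress and to handling of tissue, had 13 of 14 members higher with a median log2 fold change of 0.41 (adjusted p 4.15e-07), led by Ier3 (1.17, SE 0.30) and Junb (0.80, SE 0.23). Hypoxia and glycolysis genes had 20 of 21 members higher, median 0.32 (adjusted p 4.62e-06), led by Aldoa and Pgam1. The other 5 lists were M1-type macrophage genes (9 of 9 members higher, median 0.66), interferon gamma response (24 of 24, median 0.48), bacterial sensing (12 of 15, median 0.39), type I interferon response (21 of 21, median 0.43) and neutrophils (11 of 11, median 0.62). Without PDL1TSE18 none of these 5 passed, with adjusted p from 0.0541 for neutrophils to 0.711 for the interferon gamma response, where the medians of the interferon gamma and type I interferon lists were 0.14 and 0.15. The neutrophil list mean of PDL1TSE18, 2.73, was close to the combination mean of 2.66. Leaving it out thus hardly moved that mean, and the lost call does not show that this tumour carried the neutrophil change. Bacterial sensing and neutrophils also failed without PDL1TSE23, where neutrophils had an adjusted p of 0.468 and a median of 0.09, and type I interferon without control tumour NC26. Without PDL1TSE18, 6 other lists passed toward lower values, adipocytes (median -0.98), skeletal muscle (-0.79), fibroblasts (-0.39), endothelial cells (-0.37), dendritic cells (-0.31) and macrophages (-0.23), with camera adjusted p from 2.26e-06 to 0.0102. Other single tumours left out brought in lists toward higher values: T cells passed without NC13 (median 0.48, adjusted p 5.12e-05), PDL1TSE1 (0.00157) or PDL1TSE23 (0.00574), as did cytotoxic, checkpoint and MHC class I lists, skeletal muscle passed without PDL1TSE1 or PDL1TSE23, fibroblasts without PDL1TSE1 (median 0.44, adjusted p 0.00998), and macrophages and MHC class II (0.00869) without PDL1TSE23. Toward lower values, proliferation passed in camera without PDL1TSE23 (median -0.10, adjusted p 0.00246) and oxidative phosphorylation without NC26 (median -0.048, adjusted p 0.0420). Of 14 focus genes of T cell immunity 0 passed in limma, also when adjusted over the list alone (smallest adjusted p 0.109). Cd274, which encodes PD-L1, had a log2 fold change of 0.81 (SE 0.49), Gzmb 0.75 (SE 0.55), Prf1 0.81 (SE 0.51), Cd8a 0.14 (SE 0.36) and Ifng 0.12 (SE 0.27), and those of Cd8a, Cd4, Ifng, Cxcl9, Ccl5, Pdcd1, Cxcl13 and H2-K1 changed sign when single tumours were left out. Adjusted over their list alone, the immediate early genes Ier3 and Junb passed in limma.

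**Figure D2:**
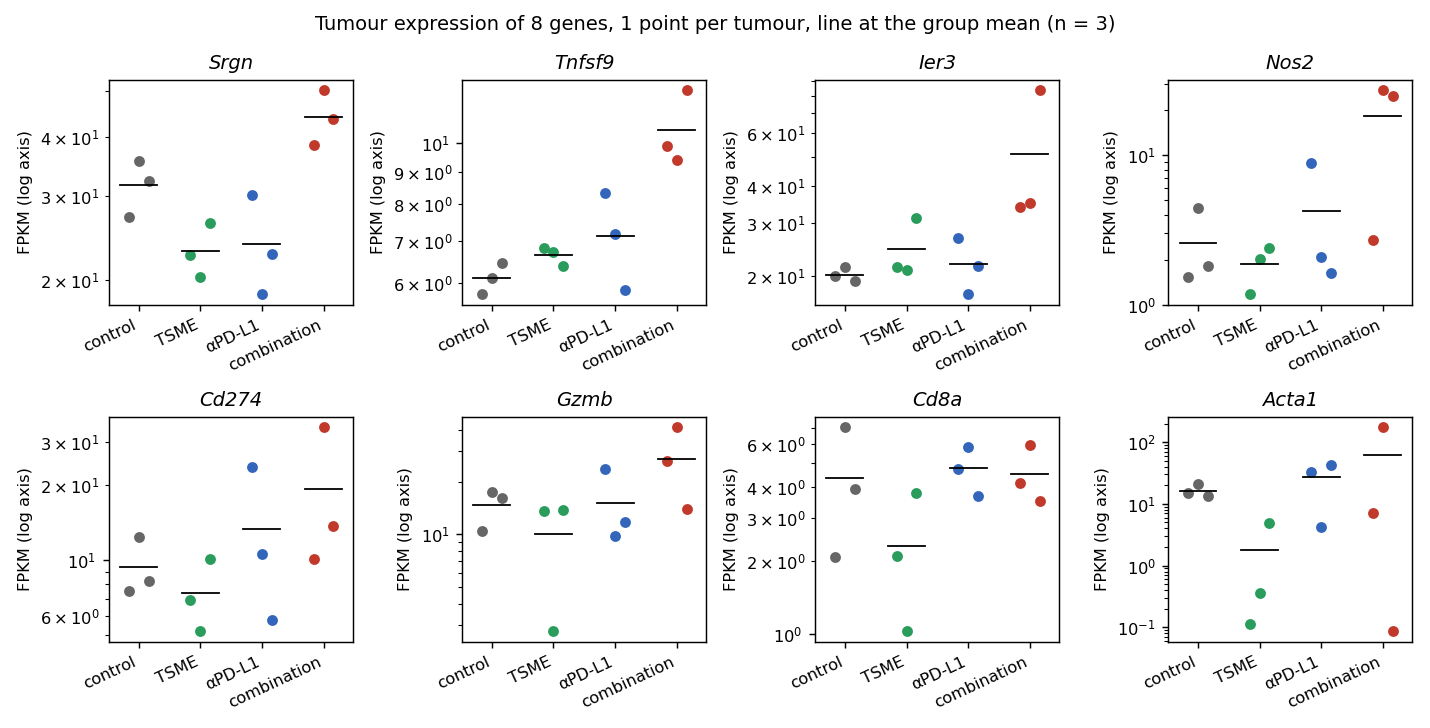
FPKM (log axis) of 8 genes in each of the 12 tumours, with a line at the group mean (n = 3 per group). Srgn and Tnfsf9 are higher in every combination tumour than in every other tumour, while Acta1 and Cd274 are highest in 1 combination tumour. Genes with the smallest p were named only if the 2 groups compared did not overlap, so this separation follows in part from that choice. In limma none of the 8 genes passed adjustment over all genes, and DESeq2 on recovered reads called Srgn against αPD-L1, against TSME and for the interaction.

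The combination was compared with αPD-L1 alone to ask what the bacteria added to the antibody. Srgn, the proteoglycan of secretory granules in leukocytes, had the smallest p of the genes that were higher (log2 fold change 0.88, SE 0.17), with 38.5 to 50.1 FPKM in combination tumours against 18.6 to 30.2 under αPD-L1. Pnrc1 (0.70, SE 0.14), Rara (0.34, SE 0.08), Tnfsf9 (0.50, SE 0.12) and the protease gene Furin (0.32, SE 0.08) followed. Mitochondrial mt-Tn (-1.99, SE 0.37), Itpa, the mitotic kinase Haspin, the kinetochore gene Nuf2 and Nucks1 lay lower. Here limma called 0 genes (smallest adjusted p 0.902), with 589 at an unadjusted p under 0.05, edgeR called 0 with 617, and DESeq2 on recovered reads called 3, Pnrc1, Srgn and 1810026B05Rik. Camera with the preset correlation placed 8 lists higher and 1 lower, and with an estimated correlation 0 lists passed (adjusted p of the 9 lists 0.602 to 0.935). Hypoxia and glycolysis genes had 20 of 21 members higher (median 0.46, adjusted p 1.89e-10), immediate early genes 14 of 14 (median 0.40, adjusted p 1.51e-07) and neutrophil genes 11 of 11 (median 0.80, adjusted p 8.19e-07), and all 20 proliferation genes were lower (median -0.17, adjusted p 1.92e-06), with Plk1 at -0.23 (SE 0.07) and Mki67 at -0.26 (SE 0.11). These 4 lists passed whichever single tumour was left out, with medians that ranged from 0.21 to 0.63 for hypoxia and glycolysis, 0.26 to 0.60 for immediate early genes, 0.45 to 1.34 for neutrophils and -0.27 to -0.08 for proliferation. The neutrophil list mean was 3.75 in PDL1TSE23 and 2.73 in PDL1TSE18, around a combination mean of 2.66. This places PDL1TSE1 below the αPD-L1 mean of 1.60, so not every combination tumour shared the neutrophil rise. Type I interferon response, bacterial sensing, M1-type macrophage, fibroblast and mast cell lists failed without PDL1TSE18, with adjusted p from 0.156 to 0.490, where the fibroblast list had a median of -0.15 in place of 0.36. All of them except bacterial sensing also failed without other single tumours, M1-type macrophages and fibroblasts without PDL117, type I interferon without PDL115, and mast cells without PDL1TSE23, PDL117 or PDL115. The list mean of PDL1TSE18 was 3.77 for mast cells against 3.69 in the combination group, and 3.52 against 3.32 for bacterial sensing. For mast cells and bacterial sensing the lost call thus does not show that this tumour carried the change. Without PDL1TSE18, 6 other lists passed toward lower values, among them T cells (median -0.23), MHC class II (-0.57), macrophages (-0.31) and skeletal muscle (-1.01). Toward higher values T cells passed without PDL1TSE1 (median 0.30, adjusted p 0.0042) or PDL1TSE23 (0.0108), cytotoxic genes without either of these or PDL14, and skeletal muscle (median 0.92) and macrophages without PDL1TSE23. Interferon gamma genes passed higher without PDL1TSE1, PDL1TSE23 or PDL14 (3.32e-06) and lower without PDL115 (0.0224). Of 14 focus genes 0 passed in limma, also when adjusted over the list alone (smallest adjusted p 0.676).

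The antibody alone was compared with control. Genes with the smallest p were Abhd14b (log2 fold change 0.26, SE 0.07), Dpm2, Fbxl15, Fam160a1 and Myadm toward higher values, and Dnajb9, a chaperone of the endoplasmic reticulum (-0.32, SE 0.07), Tef, the matrix protein gene Mgp (-1.20, SE 0.34), Snhg8 and Acsbg1 toward lower ones. In limma 0 genes passed (smallest adjusted p 1.0), 270 had an unadjusted p under 0.05, and edgeR (249 unadjusted) and DESeq2 called 0. The 270 are fewer than the 634 that chance gives. One estimate of the spread served all 4 groups, so tumours outside the pair, PDL1TSE18 included, entered these p. Limma also called 0 with any single tumour left out, and the 0 calls do not show that the antibody had no effect. Proliferation genes had 19 of 20 members higher with a median of 0.14 (camera adjusted p 6.83e-06), a call kept with any single tumour left out (medians 0.07 to 0.16). With estimated correlation the adjusted p was 0.950 for this list and the 3 others called, mast cells, fibroblasts and interferon gamma. Mast cell genes had 6 of 6 members lower (median -0.39) and fibroblast genes 17 of 18 (median -0.32), and neither passed without αPD-L1 tumour PDL117 (adjusted p up to 0.110 and 0.632 over the tumours left out). Interferon gamma genes had 23 of 24 members higher (median 0.28), but the median ranged from -0.17 to 0.76 as single tumours were left out. T cell and cytotoxic lists did not pass, but without control tumour NC13 T cells (median 0.30, adjusted p 0.000899), cytotoxic (0.0144), checkpoint (0.00926) and MHC class I and II lists passed toward higher values. Type I interferon passed lower without PDL14 (7.36e-06) and higher without NC13 or PDL115. Cd274 had a log2 fold change of 0.29 (SE 0.49); 0 of 14 focus genes passed in limma, also when adjusted over the list alone (smallest adjusted p 0.493).

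The bacteria alone were compared with control. Fam110a (log2 fold change 0.30, SE 0.07), Tmem171, Taf4, Hic1 and Pcdh18 had the smallest p toward higher values, and Arl4d (-1.30, SE 0.34), the stress-induced mTOR inhibitor Ddit4 (-1.09, SE 0.30), Dus2, the glucocorticoid-induced kinase Sgk1 (-1.03, SE 0.33) and Hspb7 toward lower ones. By limma 0 genes passed (256 at an unadjusted p under 0.05), by edgeR 0 (244 unadjusted), and by DESeq2 2, the muscle genes Myot and Trdn. The 256 are again fewer than the 634 of chance, with the same shared estimate of the spread. Camera with preset correlation placed proliferation genes higher (20 of 20 members, median 0.11, adjusted p 6.72e-06) and 13 lists lower, and with an estimated correlation none of the 14 passed (adjusted p 0.612 to 0.806). Adipocyte genes had 6 of 6 members lower (median -1.17, adjusted p 6.72e-06; Adipoq -1.04, SE 0.38) and skeletal muscle genes 11 of 11 (median -0.98; Acta1 -3.03, SE 1.51), and these and the proliferation list passed with any tumour left out. T cell genes had 16 of 16 members lower (median -0.43, adjusted p 1.34e-05), as had 8 of 8 MHC class II genes (median -0.58), 14 of 15 cytotoxic genes (median -0.32), 10 of 10 checkpoint genes and 6 of 6 mast cell genes. The remaining lower lists were dendritic cells, MHC class I, interferon gamma response, bacterial sensing, neutrophils and tertiary lymphoid chemokines. Control tumour NC13 held high immune levels, and without it the T cell list had an adjusted p of 0.229; each of the other lower lists except mast cells, adipocytes and muscle also failed without NC13, and the mast cell list failed without TSME tumour TSE28 (0.0826). Type I interferon passed higher without NC13 (median 0.37, adjusted p 0.000559), fibroblasts and endothelial cells lower without TSE28, and hypoxia and glycolysis lower without TSE29. Of 14 focus genes 0 passed in limma, also when adjusted over the list alone (smallest adjusted p 0.585).

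The combination was compared with the bacteria alone to ask what the antibody added. Srgn (log2 fold change 0.91, SE 0.17), Nfil3 (0.84, SE 0.16), Tnfsf9 (0.58, SE 0.12), the microtubule-severing gene Katna1 and the GTPase gene Rhoc had the smallest p toward higher values, and Itpa, Upf3b, Kifc5b, Snord104 and Pcdh18 toward lower ones. In limma 0 genes passed (smallest adjusted p 0.736) and 789 had an unadjusted p under 0.05. EdgeR called 0 with 979 unadjusted, while DESeq2 called 8: Rhoc, Srgn, Zfp36, Nfil3, Pik3r5, Slc2a3, Myot and Trdn. The cytotoxic granule genes Prf1 (1.59, SE 0.51) and Gzmb (1.47, SE 0.55) and Cd274 (1.13, SE 0.49) were higher without passing, and 0 of 14 focus genes passed when adjusted over the list alone (limma, smallest adjusted p 0.0995). Camera with preset correlation placed 18 lists higher and proliferation lower, and with an estimated correlation none of the 19 passed (adjusted p 0.312 to 0.687). The lists that passed with any tumour left out were interferon gamma response (24 of 24 members higher, median 0.81, adjusted p 3.92e-09; median 0.39 without PDL1TSE18), hypoxia and glycolysis (18 of 21, median 0.43), bacterial sensing (14 of 15, median 0.55), immediate early genes (14 of 14, median 0.48), neutrophils (11 of 11, median 0.95), M1-type macrophages (9 of 9, median 0.65) and MHC class I (14 of 14, median 0.42). With single tumours left out the medians ranged from 0.53 to 1.53 for neutrophils, 0.36 to 1.09 for M1-type macrophages and 0.23 to 0.61 for MHC class I. Combination tumour PDL1TSE1 had a neutrophil list mean below the TSME mean of 1.61, so it did not share the neutrophil rise. Adjusted over their list alone, 5 bacterial sensing genes, Acod1 (1.72, SE 0.47), Tnfaip3 (1.02, SE 0.29), Nlrp3, Nfkbia and Irak3, and 1 immediate early gene, Zfp36 (0.73, SE 0.16), passed in limma. Without PDL1TSE18 the calls ended for T cells (adjusted p 0.0649), cytotoxic cells (0.238), checkpoints (0.185), MHC class II (0.464), skeletal muscle (0.843), proliferation (0.0518) and the dendritic cell, lymphoid chemokine, type I interferon, mast cell, adipocyte and p53 lists. Fibroblasts (median -0.47), endothelial cells and macrophages then passed toward lower values. All 3 passed toward higher values without PDL1TSE23 (adjusted p 0.0196, 0.0264 and 0.000882), as did fibroblasts without TSE28 (median 0.44) or PDL1TSE1 (0.59).

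The interaction asked whether both treatments together differed from the sum of each alone on the log scale. Srgn had the smallest p (1.32, SE 0.24), with Katna1, Rhoc, Rnf149 and Mapk11 also toward higher values and the mitotic kinase Plk1 (-0.41, SE 0.11), Nrm, Suv39h1, Fam110a and Marveld1 toward lower ones. The Srgn value exceeds its log2 fold changes against αPD-L1 and against TSME. Both single treatments thus lay below control for Srgn, which adds to its interaction. By limma 0 genes passed, with 388 at an unadjusted p under 0.05, by edgeR 0 with 446, and by DESeq2 3, Srgn, Myot and Trdn. All 20 proliferation genes had a negative interaction (median -0.25, camera adjusted p 1.61e-10), and with an estimated correlation none of the 19 called lists passed (adjusted p 0.329 to 0.677). Plk1 passed in limma when adjusted over the proliferation list alone. Positive interactions kept with any tumour left out were those of hypoxia and glycolysis (median 0.57), neutrophils (1.16), bacterial sensing (0.47), mast cells (0.73) and immediate early genes (0.47). Leave-out medians ranged from 0.29 to 0.68 for hypoxia and glycolysis, 0.44 to 0.94 for mast cells, 0.34 to 0.72 for immediate early genes and -0.33 to -0.15 for proliferation. For neutrophils, the list mean of combination tumour PDL1TSE1 lay below those of the αPD-L1 and TSME groups. The other 13 of the 18 positive lists, among them T cells, cytotoxic cells, interferon gamma response and adipocytes, ended without PDL1TSE18, with adjusted p from 0.194 to 0.967. Macrophages and endothelial cells passed toward negative values without PDL1TSE18 (medians -0.30 and -0.31) and toward positive values without PDL1TSE23 (0.22 and 0.21), and MHC class II passed toward positive values in 6 leave-outs. Of 14 focus genes 0 passed in limma, also when adjusted over the list alone (smallest adjusted p 0.428).

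The fold changes of 1 treatment with and without the other were compared across genes. The comparisons of combination against αPD-L1 and of TSME against control share no tumour. Across 12682 genes their log2 fold changes had a Pearson correlation of -0.09 and a Spearman correlation of -0.04. Of 100 regroupings of the tumours, the real one included, 61 gave as high a Pearson value. For the antibody effect with and without TSME the values were -0.01 and 0.09, with 45 of 100 regroupings as high. Genes are not independent replicates, so the regroupings, not the number of genes, set the scale.

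In faeces, composition was compared first as a whole, by Bray-Curtis distance between ASV shares. The 4 groups accounted for 23.6% of the variation between mice (permutation test of distances, F 2.05, p 0.0053 over 10000 permutations, n = 6 per group). Groups drawn at random also account for some variation, so the permutations, not the share alone, set the scale. Exact permutation of pairs gave 29.7% for combination against control (adjusted p 0.0216), 21.1% for TSME against control (0.0379), 19.8% for combination against αPD-L1 (0.0469), 11.4% for αPD-L1 against control (0.254) and 8.17% for combination against TSME (0.541). Mean distances were 0.488 between control mice, 0.650 between TSME mice, 0.530 between αPD-L1 mice and 0.570 between combination mice, and between groups 0.656 for control and combination, 0.645 for control and TSME, 0.613 for αPD-L1 and combination, 0.526 for control and αPD-L1 and 0.601 for TSME and combination. Control and TSME mice were thus no farther apart than TSME mice from each other, and a difference in spread between groups also enters this test. All faecal tests take the mice of a group as independent. The labels give no cage, so any effect of shared housing within a group could not be separated from treatment. The call for combination against αPD-L1 ended with 12 of 24 single mice left out, at genus level and with Jaccard or Aitchison distance, that for combination against control with Jaccard distance, and that for TSME against control with 4 of 24. Permutation within mouse numbers as a block, with only 64 regroupings, gave an adjusted p of 0.156 for each of these 3 pairs. Even at the smallest possible p of 0.0312, 3 of 5 pairs alone would not pass. Their adjusted p would then be below 0.156, so the number of regroupings does not by itself account for this value. Shannon diversity averaged 3.58 in control, 3.40 under TSME, 3.79 under αPD-L1 and 3.40 in the combination, and no pair passed by exact permutation (smallest adjusted p 0.552). The number of ASVs at equal depth averaged 256, 218, 254 and 252 in the same order (smallest adjusted p 0.687).

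**Figure D3:**
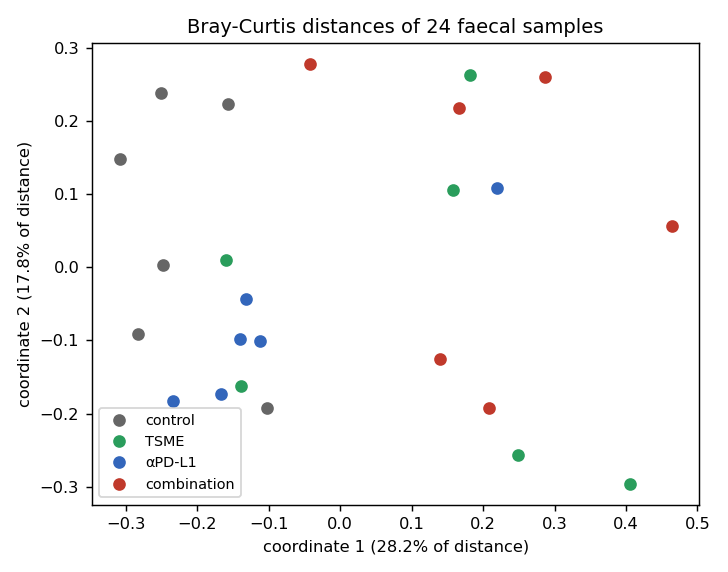
Principal coordinates of Bray-Curtis distances between the faecal samples of 24 mice (n = 6 per group), with 28.2% of the variation on coordinate 1 and 17.8% on coordinate 2. The 4 groups account for 23.6% of the variation (permutation test of distances, p 0.0053), and groups drawn at random also account for some.

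Combination mice were compared with control mice genus by genus. In edgeR 3 of 66 genera passed, all of them rare. Parvibacter, a member of the Actinobacteriota, was absent from all 6 control mice and had 264 reads in 3 of 6 combination mice (log2 fold change 8.44, SE 2.33, adjusted p 0.0186, at least 75.7-fold higher). Pseudomonas (-7.09, SE 1.91, at least 39.9-fold lower) and Flavobacterium (-6.96, SE 1.86, at least 33.7-fold lower), genera common in water and soil, had 103 and 87 reads in control and none in any combination mouse (edgeR adjusted p 0.0186 for each). A fit on the 2 groups alone called only Akkermansia. Exact permutation of shares over all 66 genera called 0, but at its smallest possible p of 0.00216 no genus alone could pass. Parvibacter, with reads in 3 of 6 combination mice, could not reach that p, so this 0 says little about the edgeR calls. Single mice ended these calls: edgeR called 0 without combination mouse 2 or 4, and only Parvibacter without mouse 1 or 6.

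Among common genera, Lactobacillus, which makes lactic acid, differed by -31.2 percentage points of reads between combination and control, the Muribaculaceae by 15.2 (exact permutation adjusted p 0.106) and Akkermansia, which lives on mucus, by 14.3. Akkermansia made up 14.6% ± 15.0 (SD, n = 6) of reads in combination mice, 15.6% ± 20.2 under TSME, 5.32% ± 8.75 under αPD-L1 and 0.311% ± 0.528 in control, and 5 of 6 combination mice lay above the highest control mouse. Lactobacillus made up 13.6% ± 12.1 in combination mice, 19.3% ± 19.1 under TSME, 32.3% ± 12.9 under αPD-L1 and 44.9% ± 13.1 in control. Neither Akkermansia nor Lactobacillus passed in edgeR: Akkermansia had a log2 fold change of 5.71 (SE 1.73, adjusted p 0.0522) and Lactobacillus -1.84 (SE 0.79, adjusted p 0.268). Akkermansia was called by DESeq2, by limma on centred log-ratios and by edgeR with library totals. Exact permutation of shares adjusted over the 14 fixed genera only, chosen after the data were seen, gave an adjusted p of 0.0404 each for Akkermansia, Lactobacillus and Muribaculum, which stood at 2.22% ± 1.01 in the combination and 0.716% ± 0.287 in control. Of reads other than Akkermansia, Lactobacillus made up 15.8% in the combination and 45.0% in control (exact permutation p 0.0108). Bacteroides made up 3.72% ± 1.91 in the combination and 6.01% ± 7.46 in control and did not pass.

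**Figure D4:**
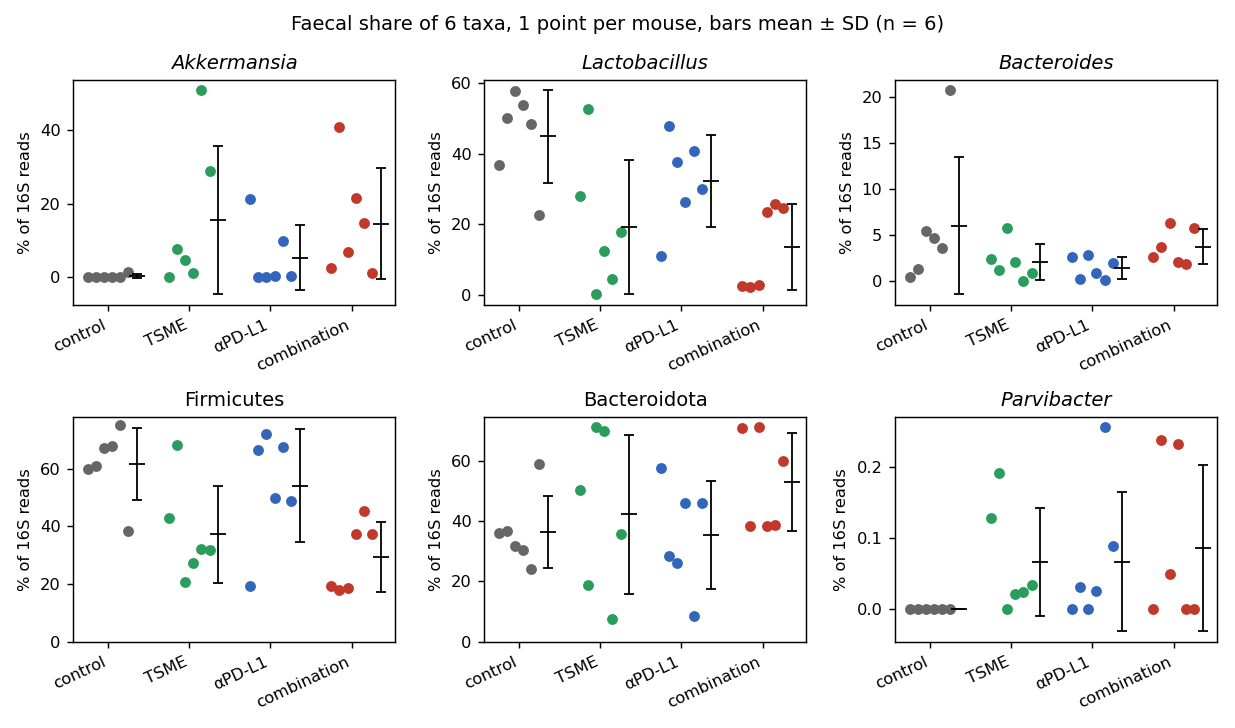
Share of 16S reads (percent) of 4 genera and 2 phyla in each of the 24 mice, with group mean and SD (n = 6 per group). Lactobacillus lies between 22.5% and 57.8% in control mice, and 3 combination mice lie below that range.

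At phylum level, with exact permutation tests chosen after the data were seen, Firmicutes fell and Verrucomicrobiota rose in combination against control. Firmicutes made up 61.6% ± 12.6 of reads in control, 37.2% ± 16.9 under TSME, 54.1% ± 19.5 under αPD-L1 and 29.3% ± 12 in the combination (difference from control -32.3 points, adjusted p 0.0108). Verrucomicrobiota, nearly all Akkermansia, differed by 14.3 points (adjusted p 0.0108). Bacteroidota stood at 52.9% ± 16.4 in the combination and 36.4% ± 12 in control (adjusted p 0.0974). For TSME against control, Firmicutes (-24.4 points), Verrucomicrobiota (15.2) and Actinobacteriota (1.35) each had an adjusted p of 0.0577, and no phylum passed in the other pairs.

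Combination mice were compared with αPD-L1 mice for what the bacteria added. Flavobacterium was the only genus of 66 that passed in edgeR (log2 fold change -6.86, SE 1.85, adjusted p 0.0438, at least 28.8-fold lower), with 83 reads under αPD-L1 and none in the combination. It no longer passed with DESeq2 size factors, with library totals, with mouse numbers as a block or with 20 of 24 single mice left out. Pseudomonas (-6.0, SE 1.80) and Turicibacter, an inhabitant of the small bowel (6.77, SE 2.11), had an edgeR adjusted p of 0.0558 each. Akkermansia (1.20, SE 1.43) and Lactobacillus (-1.44, SE 0.78) did not pass.

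For αPD-L1 against control edgeR called 0 of 66 genera, with 9 at an unadjusted p under 0.05, and DESeq2 called 5, Akkermansia, Enterorhabdus, Gastranaerophilales, Lachnoclostridium and Parvibacter. Parvibacter (log2 fold change 8.27, SE 2.31) and Lachnoclostridium, a butyrate-producing group (3.96, SE 1.18), had an edgeR adjusted p of 0.0541 each, and Enterorhabdus (2.35, SE 0.77) one of 0.0692. Without αPD-L1 mouse 5 the values were 6.63 for Parvibacter, 1.88 for Lachnoclostridium and 1.18 for Enterorhabdus.

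For TSME against control edgeR called 0, with 7 at an unadjusted p under 0.05, and DESeq2 called 3, Akkermansia, Candidatus Saccharimonas and Parvibacter. Parvibacter, with 202 reads in 5 of 6 TSME mice, had a log2 fold change of 8.28 (SE 2.31, edgeR adjusted p 0.0636), Akkermansia 6.16 (SE 1.76, 0.0668) and Lachnospiraceae NK4B4 6.63 (SE 2.31, 0.114). At the level of ASVs edgeR called 13.

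For combination against TSME edgeR called 0 of 66, with 2 genera at an unadjusted p under 0.05, Pseudomonas (log2 fold change -5.56, SE 1.76) and Flavobacterium (-5.21, SE 1.69; adjusted p 0.125 each), and DESeq2 called 0. For the interaction edgeR called 0, with 11 at an unadjusted p under 0.05. Lachnoclostridium (-5.58, SE 1.58), Enterorhabdus (-3.33, SE 1.06) and Turicibacter (8.22, SE 2.63) had an edgeR adjusted p of 0.0662 each, and these 3 were called by DESeq2. With single mice left out Lachnoclostridium ranged from -6.03 to -2.49.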

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

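A rule comparing each mouse with the other 5 of its group placed 31 values of 116 groups far above the rest of their group, all at the high end, where chance gives about 1 in 20 groups of normally distributed values. Shares here are skewed with many zeros, so that this share need not hold, and Verrucomicrobiota and Akkermansia count nearly the same reads. The weighing that follows uses tests chosen after the results were seen, except the list of 23 background genera, and the prediction for splits of adjusted ASV presence was also written before their result, although that test was chosen after the pattern was seen. αPD-L1 mouse 5 had 57930 total reads and high shares of Actinobacteriota (9.53%), Enterorhabdus (9.13%), Lachnoclostridium (6.72%), Parvibacter (0.255%) and Blautia (0.250%). Control mouse 6 was high for Bacteroidota (59.0%), Bacteroides (20.7%), Verrucomicrobiota (1.38%) and Akkermansia (1.38%), and control mouse 1 for Actinobacteriota (2.70%) and Enterorhabdus (2.56%). Combination mouse 1 was high for Alistipes (21.1%), Patescibacteria (5.08%) and Lachnoclostridium (1.39%), mouse 2 for Turicibacter (0.809%), mouse 3 for Ruminococcus (0.696%), Faecalibaculum (0.411%) and Enterococcus (0.268%), mouse 4 for unclassified Bacilli (9.30%), and mouse 5 for Roseburia (0.124%) and Lachnospiraceae NK4B4 (0.101%). TSME mouse 3 was high for Roseburia (0.373%), Ruminococcus (0.308%) and Lachnospiraceae NK4B4 (0.125%), and TSME mouse 6 for Lachnoclostridium (3.19%). Further values were Ruminococcus in control mouse 4 (0.0875%) and αPD-L1 mouse 6 (0.0502%), Turicibacter in αPD-L1 mouse 4 (0.0118%), and Lachnospiraceae NK4B4 (0.236%) and Escherichia-Shigella (0.0356%) in αPD-L1 mouse 3.

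Tumour PDL1TSE18 stood apart from the other tumours. All 11 skeletal muscle genes were highest in it, as muscle in the sample would give. This restates the high mean of the list that prompted the question, so it is no separate test of the source. The highest of 7 lymph node genes reached 0.832 FPKM, which speaks against a lymph node as source of the immunoglobulin genes. The higher Igkc value of the other 2 combination tumours was 10.4 FPKM against 41.8 in the highest control, so plasma cells did not rise in every combination tumour, and a response in 1 mouse remains open.

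Pseudomonas and Flavobacterium had no read in combination mice. At the share of the other 18 mice 62.8 and 68.4 reads were expected, so depth is an unlikely cause. No mouse held over 31 reads of either genus. Reads of other genera on the background list occurred in 5 of 6 combination mice and 17 of 18 others (Fisher p 0.446), and those of 4 water and soil genera, chosen after the reads were seen, in 1 of 6 and 13 of 18 (Fisher p 0.0501). Background sequences that differed between sample sets may explain the absence, and these tests cannot tell that from a loss under treatment.

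Counts of calls were compared with splits of the same samples. The numbers of splits given include the real grouping. For genes the real count was 0 in each comparison. Every split reaches 0, so the 10 of 10 splits in the 5 pairs and 100 of 100 for the interaction test nothing. The highest other counts were 0 for combination against control, 126 against αPD-L1, 0 for αPD-L1 and 1 for TSME against control, 2 for combination against TSME and 1 for the interaction. The split with 126 genes set PDL1TSE18, PDL1TSE23 and PDL14 against PDL1TSE1, PDL117 and PDL115. It points to a structure of the samples across both treatments, whose cause was not tested and which chance among 10 splits may also give. For gene lists 7, 9, 4, 14 and 19 calls in the 5 pairs were reached by 10, 10, 9, 3 and 1 of 10 splits (highest other 17, 20, 16, 14 and 18), too few splits for a share under 0.05, and 19 in the interaction by 7 of 100 (highest other 21).

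For faecal genera the 3 calls of combination against control were reached by 1 of 100 splits, the real grouping itself (highest other 2). The 1 call against αPD-L1 was reached by 12 of 100 (highest other 4). The 0 calls elsewhere were reached by 100 of 100, as any split must (highest other 3, 1, 3 and 4). Presence of ASVs in the 12 TSME-given and 12 other mice gave 0 of 388 past adjustment (smallest adjusted p 0.222). This was reached by 100 of 100 splits, as any split must (highest other 1). The number at an unadjusted p under 0.05, chosen after the adjusted number was 0, was 24. It was reached by 1 of 100 splits, the real grouping itself (highest other 21).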

How the results depend on the processing

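Recovered-read DESeq2 and bare genus names were chosen only after the results were seen; the cause of the changes below was not tested. Without a filter on low values limma called 2, 1, 3, 5, 2 and 2 tumour genes in place of 0 (combination against control, against αPD-L1, αPD-L1 and TSME against control, combination against TSME, interaction), and DESeq2 on recovered reads 3 (combination against αPD-L1), 2 (TSME against control), 8 (combination against TSME) and 3 (interaction). Leaving out single tumours gave 0 to 1 for TSME against control and 0 to 2 for combination against TSME. Camera with an estimated correlation and fry called 0 lists in all 6 comparisons, and leave-outs gave 7 to 15, 6 to 16, 4 to 13, 5 to 15, 10 to 21 and 8 to 21. The mouse-number block was not run for tumours, since their columns cannot be matched to mouse numbers.

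In combination against control H2-K1 reversed to -0.0309 under quantile normalization, and library weights gave H2-K1 -0.0916, Cxcl9 -0.00682, Cxcl13 -0.37, Cd4 -0.12 and Ifng -0.0250. Against αPD-L1 library weights gave H2-K1 -0.0860, Cxcl9 -0.33 and Cd4 -0.00516. Leave-out ranges against control were H2-K1 -0.20 to 0.29, Cxcl9 -0.29 to 0.65, Ccl5 -0.0622 to 1.42, Pdcd1 -0.0230 to 0.56, Cxcl13 -0.68 to 0.97, Cd8a -0.21 to 0.49, Cd4 -0.43 to 0.68 and Ifng -0.16 to 0.31. Against αPD-L1 they were H2-K1 -0.14 to 0.35, Cxcl9 -0.52 to 0.61, Ccl5 -0.22 to 1.27, Pdcd1 -0.24 to 0.20, Cd8a -0.24 to 0.0724, Tnf -0.00304 to 0.43 and Cd4 -0.34 to 0.77. Lists whose camera direction reversed in a leave-out had medians from -0.15 to 0.67 (fibroblasts, combination against αPD-L1) and -0.17 to 0.76 (interferon gamma, αPD-L1 against control), and in the interaction -0.0196 to 0.79 (type I interferon), -0.15 to 0.89 (fibroblasts) and -0.14 to 1.80 (muscle). Type I interferon (0.0471 to 0.67) and adipocytes (0.27 to 1.24) in combination against TSME turned in camera direction while their medians stayed positive. The M2-type macrophage median in the interaction ranged from -0.0952 to 0.66 with its camera direction kept. The similarity ranged from -0.196 to 0.178 for TSME and -0.241 to 0.134 for αPD-L1.

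The 1 genus called for combination against αPD-L1 became 0 with DESeq2 size factors, library totals, no filter, the mouse-number block, ASVs, exact permutation of shares and a fit on 2 groups, 5 with DESeq2 and 2 with limma on centred log-ratios. The 3 against control became 1 with ASVs, 0 with exact permutation and 1 with a fit on 2 groups, and 4 with library totals and with DESeq2, both adding Akkermansia. Limma on centred log-ratios called 3, with Akkermansia in place of Parvibacter. For αPD-L1 against control the count was 1 with ASVs, 5 with DESeq2 and 1 with a fit on 2 groups. For TSME against control it was 1 without a filter, 13 with ASVs, 3 with DESeq2, 1 with a fit on 2 groups and 1 with bare genus names. For the interaction it was 1 with ASVs, 3 with DESeq2 and 4 with bare genus names. Leave-outs gave 0 to 4, 0 to 2, 0 to 2, 0 to 2, 0 to 1 and 0 to 3. Akkermansia in combination against TSME reversed to 0.86 with the block and 0.28 with centred log-ratios (leave-outs -1.27 to 0.70), and Lactobacillus in the interaction ranged from -0.89 to 0.52.

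PERMANOVA within mouse numbers as a block kept its shares (29.7%, 19.8% and 21.1%) at an adjusted p of 0.156 each. With 64 regroupings 3 of 5 pairs alone could not pass, but at the smallest possible p of 0.0312 their adjusted p would be below 0.156. Without the block PERMANOVA no longer passed against αPD-L1 at genus level (23.8%) and with Aitchison distance (10.9%). With Jaccard distance it failed against control (11.2%) and against αPD-L1 (9.75%). Leave-outs gave 16.6% to 27.9% against αPD-L1 and 18.6% to 25.7% for TSME against control, with the call lost in 12 and 4 of 24. Same-numbered mice of different groups did not resemble each other more than other mice. Deviations from the group mean had a median correlation of -0.0174 for the same number and 0.000233 for different numbers. Of 24 samples 6 correlated best with their own number, which does not decide this alone. Shannon diversity and ASV numbers kept their calls throughout.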
